A study of Drosophila melanogaster with 16 samples.

How the data were processed

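Total RNA from the fat body of mid-third-instar Drosophila melanogaster larvae was sequenced in 16 samples, per the labels. The larvae carried the fat body driver r4-GAL4 with the temperature-sensitive repressor Tub-GAL80ts, and the transgenes were expressed for 12 h at 30 °C. The 4 groups of 4 replicates were control (UAS-RFP and UAS-GFP), Toll10b (UAS-Toll10b and UAS-GFP), myrAkt (UAS-RFP and UAS-myrAkt) and Toll10b+myrAkt (UAS-Toll10b and UAS-myrAkt). RNA was extracted with a Direct-zol kit and libraries were made with the NuGEN Ovation RNA-Seq System for Drosophila. Per the submitters' processing notes, Salmon and DESeq2 and the builds BDGP6 and dm6 were used. Their roles, versions and annotation release are not given in the sources used here, nor is the strand setting of the quantification, so reads of genes that overlap on opposite strands cannot be assigned with certainty.

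The deposited values are a signal per gene and sample: gene counts divided by a size factor of the sample. This was tested on the values themselves. In each column every value was a whole multiple of the smallest step, within a tolerance of 0.01 reads, and the recovered whole reads came to 100% of the values. The recovered reads per sample ran from 10.3 to 47.5 M with a median of 17.7 M. Of 14175 gene identifiers, 13948 matched a symbol in the reference annotation (Ensembl genes on BDGP6, dm6 coordinates). The 227 unmatched identifiers held 3.24% of the reads; they stayed in the tests but were not named, so list members among them, such as Drs and InR, are not analysed here. No read was found in any sample for 859 genes.

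The design written before the data were examined named edgeR for counts and limma-trend for normalised values. Because the unit was normalised, limma-trend was used (limma 3.58.1 in R 4.3.3) on log2 of the value plus a pseudocount of 1. Genes with a value of 1 or more in at least 4 samples were tested, which left 11181. All 16 samples entered 1 fit with a mean for each of the 4 groups, and the comparisons were contrasts of these means: each single transgene against control, Toll10b+myrAkt against each single transgene and against control, and the interaction, which is the Toll10b effect with myrAkt minus the Toll10b effect without it. P-values are two-sided and were adjusted over all genes tested by the method of Benjamini and Hochberg, with a threshold of 0.05. A log2 fold change is given with its standard error (SE) and a group mean with its SD, over n = 4.

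Gene lists were also fixed before the data were examined. They cover antimicrobial peptides; Bomanins, Daisho and Baramicin; other infection-responsive genes; Toll and Imd pathway components; JAK/STAT and Turandot genes; insulin-like peptides and fat body growth signals; FoxO-responsive genes; insulin/TOR pathway components; ribosome biogenesis; cytosolic and mitochondrial ribosomal proteins; oxidative phosphorylation; aminoacyl-tRNA synthetases; cell cycle and DNA replication; fatty acid and triglyceride synthesis; lipolysis and beta-oxidation; phospholipid synthesis; endoplasmic reticulum chaperones and secretion; glycolysis; trehalose and glycogen; autophagy; larval serum and fat body secreted proteins; ecdysone response; cytochrome P450s; glutathione S-transferases; heat shock proteins; JNK and cell death; and markers of hemocytes, gut, salivary gland, muscle, gonad, neurons and imaginal disc and epidermis. A list of sex-linked dosage RNAs had 1 measured member, Sxl, and was not tested. A list of Malpighian tubule markers was added after the data had been seen. Each list was tested with camera (preset correlation between genes of 0.01, 36 lists per comparison, Benjamini and Hochberg adjustment over the lists), with camera again using an estimated correlation, and with fry in its directional form. Members past the threshold were counted over all genes and also adjusted over the list alone.

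The named genes followed a rule fixed in advance. Tl, Akt and Ilp6 are always named. For each single transgene against control, the 10 genes with the largest and the 10 with the smallest log2 fold change were taken, and 5 and 5 for the other comparisons. They had to pass the threshold, have an average log2 CPM of 3 or more, carry a symbol beyond a CG or CR number, and show no overlap between the replicates of both groups; the last condition was dropped for the interaction. From each list up to 4 members past the threshold with the largest change were taken, or the most expressed members to make 2. A few genes for which a comparison gave no call are printed from the same tables. Single-gene comparisons of Tl, Akt, Ilp6, Thor and tobi also had a two-sided exact permutation test over the 70 arrangements of 8 samples, adjusted over the 5 comparisons; the smallest p it can give is 0.029. The chromosomes of the called genes were compared with those of the tested genes by Fisher's exact test, chosen after the data had been seen.

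The alternatives tried on the counts and named genes were edgeR 4.0.16 on the recovered reads with size factors of the RLE or TMM kind, DESeq2 1.42.0, limma-voom with sample quality weights, TMM scaling or library totals in place of the size factors, no filter, a filter of 5 CPM in 4 samples, a pseudocount of 0.1, only the groups compared in the fit, the replicate number as a block, an absolute log2 fold change of at least 1, and each library left out in turn. Of 184 results of named genes, 174 had a value with the 5 CPM filter and 181 with only the groups compared, where the interaction cannot be fitted. Chosen after seeing the data were TMM scaling with the same test, edgeR with TMM, the mean levels of the salivary gland, gut and Malpighian tubule marker lists as covariates, leaving out the libraries richest in salivary gland or gut markers, and reads thinned to the smallest library. So were each pair of control libraries left out for the 3 lists of immune effector genes, and the replicate block with only the groups compared for Toll10b+myrAkt against myrAkt. No sample was left out of the comparisons reported. The test was also tried on simulated data with 200 changed genes: for Toll10b against control it recovered 28% of 2-fold and 73% of 4-fold changes, and for the interaction 4% and 56%. A fold against a group with 0 reads in all libraries is given as a lower bound against a floor of 3 reads per library. Reads carry no molecular identifiers, so floors cover counting error only.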

Results

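The fat body of the fly larva stores fat and glycogen, senses nutrients and secretes immune peptides. It was profiled by RNA sequencing in 16 samples: 4 controls, 4 with Toll10b (a constitutively active form of the immune receptor Toll), 4 with myrAkt (a membrane-tethered, active form of the insulin pathway kinase Akt) and 4 with both transgenes. The title of the series places the work in how Toll signalling lowers growth through the insulin-like peptide Ilp6. Values are normalised read counts, with each group given as mean ± SD over n = 4. Recovered reads ran from 10.3 to 47.5 M per library; the Toll10b+myrAkt libraries held 36.1, 23.2, 47.5 and 18.5 M, and the largest of the other 12 held 19.7 M. The 10 most abundant genes took between 48.1% and 57.9% of each library. The labels do not state whether replicates came from separate cultures, so p-values measure the spread between these samples.

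The expressed transgenes were visible in the counts. Akt (3R:16099228-16105670 in dm6 coordinates) stood at 619 ± 46.8 in controls, 651 ± 174 in Toll10b, 6386 ± 1271 in myrAkt and 5752 ± 1237 in Toll10b+myrAkt. It was 10.2-fold higher in myrAkt than in control (log2 3.35, SE 0.20, adjusted p = 4.06e-07; exact permutation p = 0.0286, adjusted 0.0477). Tl (3R:26799041-26842403), which encodes Toll, stood at 2504 ± 887 in controls, 10720 ± 4353 in Toll10b, 4946 ± 1649 in myrAkt and 11290 ± 4006 in Toll10b+myrAkt. It was 4.08-fold higher in Toll10b than in control (log2 2.03, SE 0.39, adjusted p = 0.0235; exact permutation p = 0.0286, adjusted 0.0714), and Toll10b+myrAkt against myrAkt gave 1.17 (SE 0.39, adjusted p = 0.468). The Tl call against control was lost without control 1 (adjusted p = 0.0713), control 2 (0.0879), control 4 (0.0516), Toll10b 1 (0.0884), Toll10b 3 (0.0871) or Toll10b 4 (0.0767). It was also lost with the Toll10b and control libraries alone in the fit (0.0845).

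Ilp6 (X:2331493-2334658), the insulin-like peptide made by the fat body, stood at 1670 ± 408 in controls, 925 ± 317 in Toll10b, 1723 ± 560 in myrAkt and 1529 ± 927 in Toll10b+myrAkt. Toll10b against control gave 0.544 times the control level (log2 -0.88, SE 0.39), which did not pass the test over all genes (adjusted p = 0.422) or the exact permutation test (p = 0.0857, adjusted 0.428). The log2 fold change was 0.02 for myrAkt against control, 0.57 for Toll10b+myrAkt against Toll10b and -0.31 for Toll10b+myrAkt against control (SE 0.39 each), and none passed. The interaction was 0.55 (SE 0.55, adjusted p = 0.877).

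**Figure D1:**
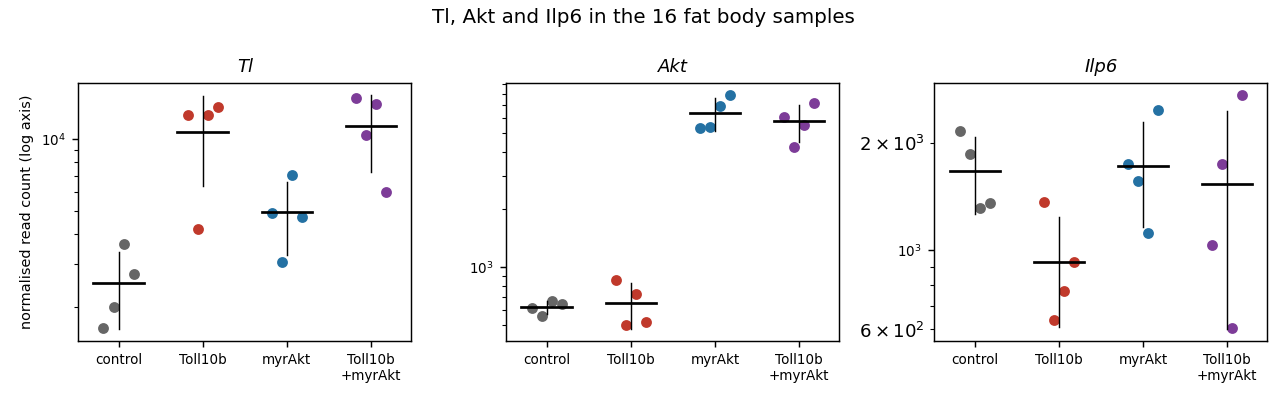
Normalised read counts of Tl, Akt and Ilp6 on log axes in the 4 groups; points are samples, bars the group mean and lines 1 SD. Akt averaged 6386 in myrAkt and 619 in controls, Tl averaged 10720 in Toll10b and 2504 in controls, and Ilp6 averaged 925 in Toll10b and 1670 in controls.

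Toll10b against control asks what active Toll did to the fat body transcriptome. The short secreted peptides that act downstream of Toll, the Bomanins, Daishos and Baramicins, rose together by up to 348-fold. BomBc1 (2R:18382704-18383235) went from 9.45 ± 4.52 to 3875 ± 2103, 348-fold (log2 8.44, SE 0.65, adjusted p = 1.8e-05). The antifungal Daisho peptide Dso1 went from 21.6 ± 18.7 to 3655 ± 2509, 187-fold (log2 7.55, SE 0.66, adjusted p = 2.84e-05). BomS3, the most abundant of them, reached 16620 ± 9977 from 708 ± 672, 35.6-fold (log2 5.15, SE 0.71, adjusted p = 0.0014; 4.49 without control 2 and 5.75 without control 4). Of the 17 measured members of the list 14 rose and none fell (15 higher adjusted over the list alone), with a median log2 fold change of 5.48 (4.94 to 6.74 over the 6 pairs of controls left out). The list passed its test (adjusted p = 5.14e-34), also with an estimated correlation (adjusted p = 0.0171). BomBc3 had 0 reads in all control libraries and 77.2 ± 105 in Toll10b, at least 20.5-fold higher (at least 6.58-fold without Toll10b 1), and the list's median was 5.17 with it at that bound. BomBc2 shares exon sequence with BomS4 and BaraA1 with CG30059, so reads at these loci may belong to the neighbour.

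Of the classical antimicrobial peptides, which depend in part on the Imd pathway, none of the 13 measured members was called singly. Drs, also on that list, had no matched identifier, so its response is not known here. All 13 measured members had positive values with a median of 1.06, and AttC gave 0.66 (SE 0.59, adjusted p = 0.705) and AttB 1.22 (SE 0.58, adjusted p = 0.442). The list passed its test (adjusted p = 0.00421) but had an adjusted p = 0.596 with an estimated correlation, and it was lost without control 1 (0.0942), control 2 (0.268) or Toll10b 3 (0.057). Its mean log2 level was 7.30, 5.95, 9.99 and 9.64 in the 4 controls. With both of the lower controls, 1 and 2, left out, its median turned negative, to -0.53 (adjusted p = 0.127). Of 19 other infection-responsive genes none passed, 16 had positive values and the median was 0.47 (adjusted p = 0.0149, adjusted p = 0.596 with an estimated correlation). That call was lost without control 1 (0.254), control 2 (0.167), Toll10b 1 (0.098), Toll10b 3 (0.0863) or Toll10b 4 (0.0714), and without controls 1 and 2 the median was -0.26 (0.431). Among 21 Toll pathway components only Tl passed, and cact, the inhibitor of the pathway, gave 1.35 (SE 0.42, adjusted p = 0.21).

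**Figure D2:**
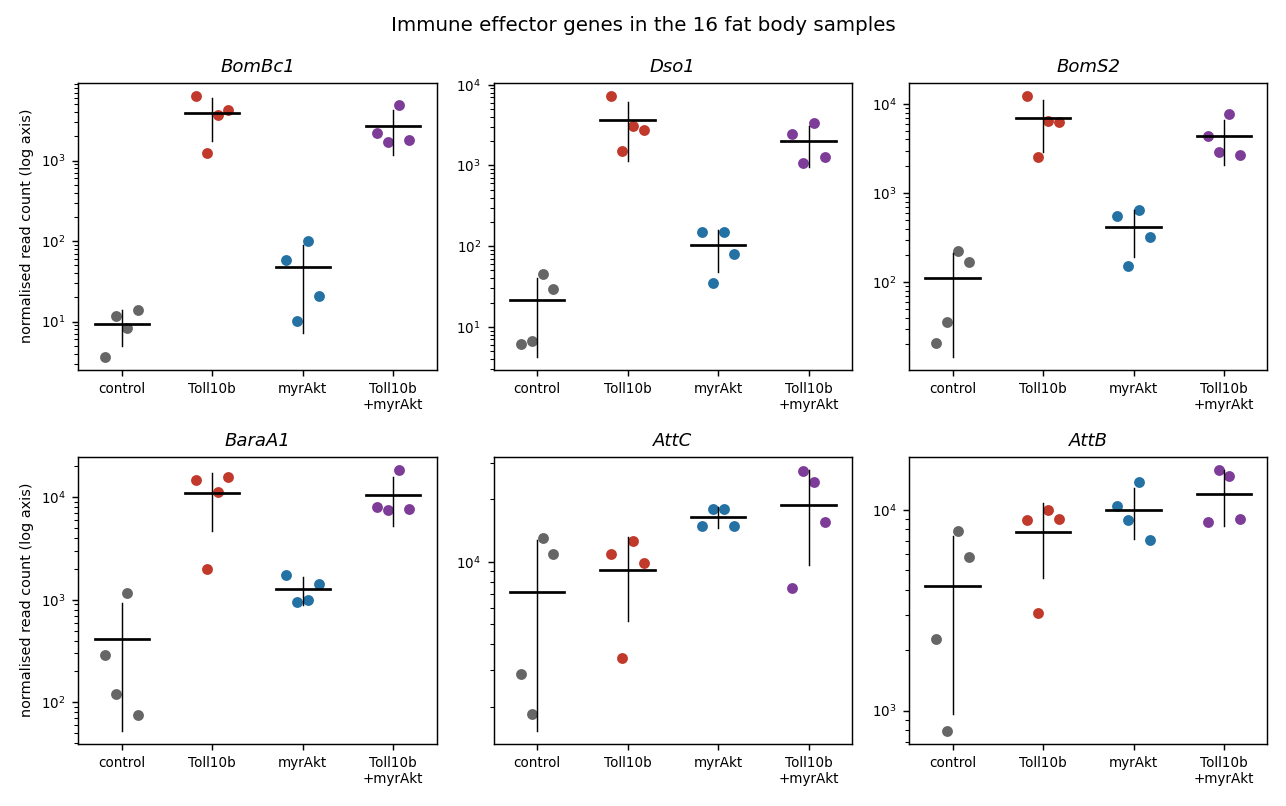
Normalised read counts of 6 immune effector genes on log axes in the 4 groups. Points are samples, bars the group mean and lines 1 SD, cut short below the lowest sample where 1 SD would reach further down. BomBc1 averaged 9.45 in controls, 3875 in Toll10b, 47.7 in myrAkt and 2662 in Toll10b+myrAkt, whereas AttC averaged 7144, 9177, 16430 and 18710.

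Outside immunity, single genes of fat breakdown and detoxification were lower in Toll10b than in control. Most genes called here outside the immune lists lay on chromosome 2, which carried the transgene that differed. For those genes line background and a response to Toll cannot be told apart. Of 13 lipolysis and beta-oxidation genes 2 fell: scu, a mitochondrial dehydrogenase of fatty acid oxidation, by 0.64 on the log2 scale (SE 0.12, adjusted p = 0.02), and the peroxisomal oxidase Acox57D-d by 0.91 (SE 0.19, adjusted p = 0.0349). These calls were lost in 3 and 7 of 16 fits with a library left out (adjusted p up to 0.0799 and 0.109) and under library totals. Over the list alone 6 fell, the median was -0.57 and the list passed (adjusted p = 5.92e-08, adjusted p = 0.267 with an estimated correlation). Among 81 cytochrome P450s, enzymes of hormone and toxin metabolism, 6 fell and 1 rose. Cyp12d1-p fell to 0.154 times the control level (1271 ± 166 to 207 ± 82.4; log2 -2.70, SE 0.30, adjusted p = 0.000302), Cyp6a23 to 0.338 times (log2 -1.56, SE 0.20, adjusted p = 0.000668) and Cyp6a2 rose 19.1-fold (log2 4.25, SE 0.73, adjusted p = 0.00903); these 3 lie on chromosome 2R. The P450 list passed as lower (median -0.26, adjusted p = 0.000359, adjusted p = 0.394 with an estimated correlation). The esterase alpha-Est2 fell to 0.392 times (7480 ± 505 to 2942 ± 318; log2 -1.35, SE 0.21, adjusted p = 0.00337), and of 35 glutathione S-transferases 1 fell, GstT3, to 0.495 times (log2 -1.01, SE 0.17, adjusted p = 0.00694). The receptor-like gene kek1, a feedback inhibitor of EGF receptor signalling, fell to 0.101 times (828 ± 259 to 86.4 ± 39.3; log2 -3.31, SE 0.60, adjusted p = 0.0133), a call lost without control 2 (0.0573) or Toll10b 1 (0.0579).

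Several growth and storage lists passed as sets after Toll10b with no member called over all genes, and each lost its call with an estimated correlation. Higher were ribosome biogenesis (24 of 25 members positive, median 0.55, adjusted p = 0.000578, adjusted p = 0.596 with an estimated correlation), mitochondrial ribosomal proteins (67 of 71, 0.34, 3.28e-08, and 0.596). Also higher were aminoacyl-tRNA synthetases (15 of 16, 0.30, 0.00407, and 0.596) and cell cycle and DNA replication (15 of 21, 0.80, 0.000578, and 0.505). Lower were insulin-like peptides and fat body growth signals (5 of 19 positive, median -0.27, adjusted p = 0.00421, adjusted p = 0.267 with an estimated correlation), autophagy (4 of 19, -0.29, 0.000772, and 0.394) and larval serum and fat body secreted proteins (2 of 9, -0.43, 0.0244, and 0.394). The storage protein gene Lsp1beta gave -0.32 (SE 0.23, adjusted p = 0.629). Also lower were cytosolic ribosomal proteins (10 of 83 positive, median -0.10, adjusted p = 3.64e-07, adjusted p = 0.594 with an estimated correlation), fatty acid and triglyceride synthesis (8 of 23, -0.14, 0.0487, and 0.505), glycolysis (3 of 13, -0.21, 0.0128, and 0.596) and trehalose and glycogen (1 of 13, -0.14, 0.0392, and 0.594). These last 4 medians turned positive when scaled by library totals, to 0.12, 0.08, 0.01 and 0.08. Leaving out 1 library ended the calls of aminoacyl-tRNA synthetases (without Toll10b 2, 0.0709), larval serum proteins (control 2, 0.0605), and glycolysis (control 1, 0.0531; Toll10b 4, 0.1). The same held for trehalose and glycogen (control 1, 0.0933; control 4, 0.0845; Toll10b 2, 0.0595; Toll10b 3, 0.12) and fatty acid synthesis (control 1, 0.0933; control 4, 0.058; Toll10b 3, 0.153; Toll10b 4, 0.17; Toll10b+myrAkt 3, 0.0596; Toll10b+myrAkt 4, 0.0526). Malpighian tubule markers were higher in Toll10b than in control (median 2.23, adjusted p = 0.0101, adjusted p = 0.596 with an estimated correlation; lost without control 4, 0.0806, or Toll10b 4, 0.0845). The median was -3.01 for salivary gland markers (adjusted p = 0.115) and -1.05 for gut markers (adjusted p = 0.177). The other lists did not pass for Toll10b: Imd pathway (median -0.03), insulin/TOR pathway (0.04), FoxO-responsive genes (-0.04), JAK/STAT (-0.10), oxidative phosphorylation (0.14), phospholipid synthesis (0.12), and endoplasmic reticulum chaperones (0.07). Nor did ecdysone response (-0.25), glutathione S-transferases (-0.12), heat shock proteins (-0.28), JNK and cell death (0.21), and markers of hemocytes (0.36), muscle (0.01), gonad (0.29), neurons (0.12) and imaginal disc (-0.56) pass. The test statistic pointed down for the insulin/TOR, muscle and neuron lists although their medians were positive, and the glutathione S-transferase list had a mean of 0.10 against its negative median.

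Across all genes, 58 were higher and 43 lower in Toll10b than in control. Of these 101 genes 25 belonged to a fixed list. Leaving out Tl and the immune lists, 57 of 86 lay on chromosome 2 (66.3% against 38.5% of tested genes; odds ratio 3.17, 95% interval 1.99 to 5.15, Fisher's exact p = 2.72e-07) and 14 on chromosome 3 (16.3% against 42.8%, Fisher's exact p = 2.41e-07). UAS-RFP of the control and UAS-Toll10b were both carried on chromosome 2. The higher genes numbered 35 without control 1, 32 without control 2, 29 without Toll10b 1, 31 without Toll10b 3 and 35 without Toll10b 4. The lower genes numbered 26 without control 1, 22 without control 2, 23 without control 4, 23 without Toll10b 1 and 28 without Toll10b 3. Library totals alone gave 66 higher and 20 lower and moved the median of all genes to 0.22. With salivary gland, gut and tubule marker levels in the fit, chosen after seeing the data, 18 and 7 passed. The replicate block gave 102 and 95, and DESeq2 121 and 92.

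The comparison of myrAkt with control asks what active Akt did without added Toll. The insulin target tobi, which encodes an alpha-glucosidase-like enzyme, rose 86.7-fold, from 6.51 ± 1.51 to 705 ± 329 (3R:25344761-25346921; log2 6.44, SE 0.40, adjusted p = 4.06e-07; exact permutation p = 0.0286, adjusted 0.0477). A pair of overlapping genes on 3R, p24-2, a cargo receptor family gene, and Unc-115b, an actin-binding protein gene, went from near silence to 345 ± 30.5 and 840 ± 81.4 (log2 7.53, SE 0.61, adjusted p = 1.32e-05, and log2 6.99, SE 0.97, adjusted p = 0.00239). With so few control reads these folds are uncertain. All p24-2 reads of the controls were in control 1, without which it was at least 90.8-fold higher, and Unc-115b gave 6.08 without control 2. The synaptic vesicle regulator cpx fell to 0.108 times the control level (641 ± 109 to 79.6 ± 49.8; log2 -3.21, SE 0.41, adjusted p = 0.00146). Smaller rises included pst, a gene known for natural variants in virus resistance (4.30-fold, log2 2.10, SE 0.27, adjusted p = 0.00146), and the adenylyl cyclase Ac76E (2.87-fold, log2 1.52, SE 0.22, adjusted p = 0.00251). The juvenile hormone epoxide hydrolase Jheh3 fell to 0.536 times (log2 -0.90, SE 0.13, adjusted p = 0.00254; not called under library totals) and the esterase alpha-Est5 to 0.512 times (log2 -0.96, SE 0.14, adjusted p = 0.0039). Exons of tobi overlap rha, so its reads may include that gene.

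Immune peptide genes had higher set levels in myrAkt than in the 4 controls together, with no member passing over all genes, but the size of this rise rests largely on controls 1 and 2. The 13 antimicrobial peptides all had positive values (median 1.92, 7 higher adjusted over the list alone, adjusted p = 5.4e-08, adjusted p = 0.615 with an estimated correlation), with AttC at 1.65 (SE 0.59, adjusted p = 0.434). Their mean log2 level was 10.56, 10.25, 10.30 and 9.29 in myrAkt, beside 9.99 and 9.64 in controls 3 and 4. Without controls 1 and 2 the median was 0.46 and the list call was lost (adjusted p = 0.154). Of 17 Bomanins, Daishos and Baramicins 15 had positive values (median 2.38, 12 higher adjusted over the list alone, adjusted p = 4e-11, adjusted p = 0.343 with an estimated correlation), with BomS3 at 708 ± 672 in control and 2179 ± 537 in myrAkt (log2 2.38, SE 0.71, adjusted p = 0.289). That list's median was 0.99 without controls 1 and 2 and ran up to 3.32 over the 6 pairs of controls left out, with the list called each time at the preset correlation. Of 13 JAK/STAT and Turandot genes 1 rose, the stress peptide gene TotC (3.74-fold, log2 1.90, adjusted p = 0.0402), a call lost in 11 of 16 fits with a library left out (adjusted p up to 0.135). In sugar metabolism 1 of 13 glycolysis genes fell, the triose phosphate isomerase Tpi (9756 ± 914 to 5612 ± 658; log2 -0.80, SE 0.15, adjusted p = 0.0215), a call lost in 6 of 16 such fits (adjusted p up to 0.0973) and under library totals. All 13 were negative, with a median of -0.35 (adjusted p = 4.7e-06, adjusted p = 0.615 with an estimated correlation). Also lower as sets were oxidative phosphorylation (4 of 70 positive, median -0.25, adjusted p = 1.89e-09, adjusted p = 0.77 with an estimated correlation) and endoplasmic reticulum chaperones (5 of 27, -0.24, 0.000175, and 0.615). So were fatty acid and triglyceride synthesis (4 of 23, -0.26, 0.000504, and 0.329) and lipolysis and beta-oxidation (2 of 13, -0.23, 0.0122, and 0.615; lost without control 4, 0.0636, or myrAkt 3, 0.148). FoxO-responsive genes passed as higher (1 of 14 called, tobi; median 0.12, adjusted p = 0.0439, adjusted p = 0.615 with an estimated correlation), but the call was lost in 9 of 16 fits with a library left out (adjusted p up to 0.208). The list's mean log2 level was 9.43 in control and 9.95 in myrAkt, a larger difference than the median of 0.12, since tobi rose. The list call therefore leans on tobi and does not show a general rise of FoxO-responsive genes. The FoxO target Thor gave 0.50 (SE 0.38, adjusted p = 0.784).

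In all, 20 genes were higher and 21 lower in myrAkt than in control, and 5 of the 41 belonged to a fixed list. Leaving out Akt, 35 of 40 lay on chromosome 3 (87.5% against 42.8% of tested genes; odds ratio 9.41, 95% interval 3.67 to 30.8, Fisher's exact p = 5.56e-09), and 2 on chromosome 2 (5% against 38.6%, Fisher's exact p = 1.68e-06). UAS-GFP of the control and UAS-myrAkt were both carried on chromosome 3, where tobi, p24-2, Unc-115b, cpx, pst, Ac76E, alpha-Est5, TotC and Tpi also lie. Without myrAkt 4 the higher genes numbered 13. Library totals alone gave 26 higher and 16 lower and moved the median of all genes to 0.12. With the other-tissue marker levels in the fit 10 and 8 passed. The replicate block gave 40 and 46, and DESeq2 54 and 79.

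**Figure D3:**
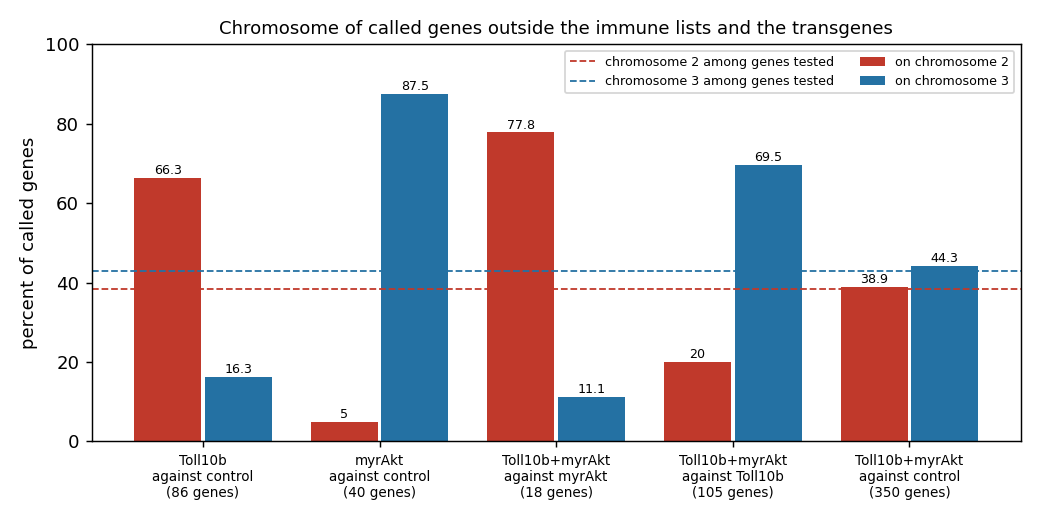
Percent of called genes on chromosomes 2 and 3 for each comparison, leaving out immune list members and the transgene's own gene, with dashed lines for the genes tested. Chromosome 2 held 66.3% of the genes called for Toll10b and chromosome 3 held 87.5% of those called for myrAkt, against 38.5% and 42.8% of the tested genes.

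Toll10b+myrAkt against myrAkt gives the Toll10b effect when Akt was active as well. Bomanin and Daisho genes rose again: BomBc1 went from 47.7 ± 41.1 to 2662 ± 1542, 68.6-fold (log2 6.10, SE 0.65, adjusted p = 0.00137), BomBc2 24.7-fold (log2 4.63, SE 0.66, adjusted p = 0.00847) and Dso1 20.3-fold (log2 4.34, SE 0.66, adjusted p = 0.0135). The Dso1 call was lost without myrAkt 2 (0.0541), myrAkt 4 (0.0531) or Toll10b+myrAkt 3 (0.0593). Of the 17 list members 5 rose, 11 adjusted over the list alone, and 16 were positive with a median of 2.96 (adjusted p = 1.87e-19, adjusted p = 0.0778 with an estimated correlation). Among those 5, BomS1 (adjusted p = 0.0493) and Dso2 (adjusted p = 0.0474) only just passed. BomBc3 had 0 reads in all myrAkt libraries and in Toll10b+myrAkt 2 and 4. Its bound of at least 5.59-fold, with which the list's median was 2.96, rests on Toll10b+myrAkt 1, without which the mean of 2.10 is under the floor of 3.39. The 13 antimicrobial peptides had a median of 0.05, with AttC at 0.03 (SE 0.59, adjusted p = 0.997). With the other-tissue marker levels in the fit that list reversed direction and passed its camera test (adjusted p = 0.0229). Among 23 genes of fatty acid and triglyceride synthesis 1 fell, ATPCL, the enzyme that makes cytosolic acetyl-CoA (18560 ± 3885 to 8708 ± 654; log2 -1.07, SE 0.20, adjusted p = 0.0474), a call lost in 14 of 16 fits with a library left out (adjusted p up to 0.21) and, like that of Cyp6a23, under library totals. Both calls also ended with the replicate number as a block in a fit of these groups alone (adjusted p = 0.072 for ATPCL and 0.077 for Cyp6a23). The list had a median of -0.23 (adjusted p = 5.27e-05, adjusted p = 0.0778 with an estimated correlation). Cyp6a23 fell to 0.449 times the myrAkt level (log2 -1.16, SE 0.20, adjusted p = 0.0283), a call lost without myrAkt 1 (0.0946), myrAkt 2 (0.111), Toll10b+myrAkt 1 (0.109) or Toll10b+myrAkt 2 (0.113).

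Also lower as sets in that comparison were cytosolic ribosomal proteins (6 of 83 positive, median -0.12, adjusted p = 1.8e-16, adjusted p = 0.33 with an estimated correlation), mitochondrial ribosomal proteins (4 of 71, -0.27, 7.65e-09, and 0.642) and oxidative phosphorylation (8 of 70, -0.22, 2.06e-07, and 0.642). The same held for glycolysis (2 of 13, -0.36, 6.59e-08, and 0.33), trehalose and glycogen (2 of 13, -0.22, 0.00111, and 0.33) and heat shock proteins (4 of 17, -0.70, 0.0151, and 0.642; lost without myrAkt 2, 0.0649, or myrAkt 4, 0.205). Cell cycle and DNA replication genes were higher as a set (15 of 21, median 0.98, adjusted p = 7.13e-05, adjusted p = 0.413 with an estimated correlation). Over all genes 14 were higher and 9 lower, and 14 of the 18 outside the immune lists lay on chromosome 2. The higher genes numbered 8 without Toll10b 1, 3 or 4, myrAkt 1 or 2, or Toll10b+myrAkt 1 or 2, and 7 without myrAkt 4 or Toll10b+myrAkt 3. The lower genes numbered 4 without any of the 4 controls or without Toll10b 3 or 4, 0 without myrAkt 1, 1 without myrAkt 2 or Toll10b+myrAkt 2, 2 without myrAkt 4 or Toll10b+myrAkt 3, 5 without Toll10b+myrAkt 1 and 22 without Toll10b+myrAkt 4. Library totals alone gave 12 higher and 3 lower. The replicate block with these groups alone gave 14 and 3, but only 7 of these 17 genes were among the 23, and 4 of the 9 calls of named genes were lost. With the other-tissue marker levels in the fit none passed.

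Toll10b+myrAkt against Toll10b gives the myrAkt effect when Toll was active as well. tobi rose 51.5-fold (6.05 ± 3.49 to 331 ± 73.7; log2 5.69, SE 0.40, adjusted p = 1.89e-06), Akt 8.90-fold and Unc-115b 209-fold (log2 7.71, SE 0.97, adjusted p = 0.000994; 7.08 without Toll10b 2 or 4 and 8.60 without Toll10b 3). The cpx level fell to 0.1 times (log2 -3.32, SE 0.41, adjusted p = 0.000902). p24-2 had 0 reads in all Toll10b libraries and 425 ± 134 in Toll10b+myrAkt, at least 116-fold higher. Sodh1, a sorbitol dehydrogenase, fell to 0.253 times (2666 ± 383 to 739 ± 326; log2 -1.99, SE 0.34, adjusted p = 0.0158). Among 13 JAK/STAT and Turandot genes TotC rose 4.78-fold and TotA rose 2.57-fold, and the feedback inhibitor Socs36E fell (log2 2.26, 1.36 and -1.49; adjusted p = 0.0126, 0.0322 and 0.0472). The last 2 calls were lost in 6 and 14 of 16 fits with a library left out (adjusted p up to 0.103 and 0.153). That list had a median of 0.86 (adjusted p = 0.0293, adjusted p = 0.321 with an estimated correlation; lost without Toll10b+myrAkt 1, 0.0777, or 3, 0.063).

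Energy metabolism genes were lower in Toll10b+myrAkt than in Toll10b as sets. For oxidative phosphorylation 64 of 70 members were negative, 58 fell adjusted over the list alone and none over all genes, with a median of -0.59 (adjusted p = 5.58e-25, adjusted p = 0.373 with an estimated correlation); the ATP synthase subunit gene ATPsynC gave -0.86 (adjusted p = 0.178). In glycolysis Tpi fell (log2 -0.76, adjusted p = 0.0288; lost in 5 of 16 fits), 10 of 13 fell adjusted over the list alone and the median was -0.66 (adjusted p = 4.83e-08, adjusted p = 0.321 with an estimated correlation). Fatty acid and triglyceride synthesis (2 of 23 fell, Acsl and Baldspot, lost in 11 and 7 of 16 fits and under library totals; median -0.42) had an adjusted p = 8.08e-05 and an adjusted p = 0.132 with an estimated correlation. Mitochondrial ribosomal proteins (0 of 71 positive, median -0.52, adjusted p = 1.81e-17, adjusted p = 0.428 with an estimated correlation) and aminoacyl-tRNA synthetases (0 of 16, -0.30, 8.08e-05, and 0.588) were lower too. So were ribosome biogenesis (0 of 25, -0.30, 0.00686, and 0.714; lost without Toll10b 2, 0.157, or Toll10b+myrAkt 2, 0.132), endoplasmic reticulum chaperones (4 of 27, -0.37, 2.59e-06, and 0.428) and heat shock proteins (3 of 17, -0.94, 0.0191, and 0.714; lost without Toll10b 2, 0.224, or Toll10b+myrAkt 1, 0.0637). The mean log2 level of heat shock proteins was 8.57 and 9.77 in Toll10b 1 and 2. It was 7.07 and 7.06 in Toll10b 3 and 4, beside a mean of 7.21 in Toll10b+myrAkt. Higher were autophagy (17 of 19 positive, median 0.35, adjusted p = 0.000369, adjusted p = 0.321 with an estimated correlation), where the kinase gene Atg1 rose (log2 1.18, adjusted p = 0.0358; lost in 6 of 16 fits and under library totals). The ecdysone response was higher too (13 of 15, 0.47, 0.00445, and 0.132), and the receptor gene EcR rose (log2 1.30, adjusted p = 0.0287; lost in 6 of 16 fits). Cytochrome P450s passed as higher (3 of 81 rose: Cyp12c1, and Cyp12e1 and Cyp9f3, lost in 8 and 6 of 16 fits; median 0.33, adjusted p = 0.0308, adjusted p = 0.546 with an estimated correlation; lost without Toll10b 1, 0.0633, Toll10b 2, 0.12, or Toll10b+myrAkt 3, 0.0803). Beside these, salivary gland markers were higher (9 of 10 positive, median 3.66, adjusted p = 0.0489, adjusted p = 0.714 with an estimated correlation; 0.573 without Toll10b+myrAkt 1), and the Bomanin list had a median of -0.41 (adjusted p = 0.0928) with BomS3 at -0.40 (adjusted p = 0.815).

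Over all genes 61 were higher and 45 lower in Toll10b+myrAkt than in Toll10b. Leaving out Akt, 73 of 105 lay on chromosome 3 (69.5% against 42.8%; odds ratio 3.08, Fisher's exact p = 4.25e-08). Sodh1, TotC, TotA, Tpi, Baldspot, Atg1, Cyp12c1, Cyp12e1 and Cyp9f3 also lie there, as do tobi, p24-2, Unc-115b and cpx. Socs36E, Acsl and EcR lie on chromosome 2. The higher genes numbered 17 without Toll10b 1, 11 without Toll10b 2, 21 without Toll10b 3, 22 without Toll10b+myrAkt 2, 18 without Toll10b+myrAkt 3 and 16 without Toll10b+myrAkt 4. The lower genes numbered 29 without control 4, 13 without Toll10b 1, 9 without Toll10b 2, 15 without Toll10b 3, 18 without Toll10b+myrAkt 2, 15 without Toll10b+myrAkt 3 and 13 without Toll10b+myrAkt 4. With the other-tissue marker levels in the fit 11 and 7 passed, and without the libraries richest in gut markers 14 and 12. Only the compared groups in the fit gave 12 and 7, the replicate block 204 and 177, and DESeq2 222 and 242.

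Toll10b+myrAkt against control gives the joint difference, and combined immune peptide genes with a drop in sugar and fat synthesis genes. BomBc1 rose 251-fold (log2 7.97, SE 0.65, adjusted p = 8.55e-06), and 13 of 17 list members rose with a median of 5.07 (adjusted p = 9.03e-22, adjusted p = 0.0464 with an estimated correlation), also 5.07 with BomBc3 at its bound of at least 5.03-fold. That bound rests on Toll10b+myrAkt 1 (mean of 2.10 without it, under the floor of 3.77). Of 13 glycolysis genes 8 fell: Tpi to 0.448 times (9756 ± 914 to 4392 ± 640; log2 -1.16, SE 0.15, adjusted p = 0.000391), Pgi to 0.482 times (16760 ± 963 to 8126 ± 1065; log2 -1.05, SE 0.21, adjusted p = 0.0112) and Ald1 to 0.539 times (34090 ± 1465 to 18640 ± 3475; log2 -0.89, SE 0.15, adjusted p = 0.00447) are examples, of which Pgi and Ald1 did not pass under library totals. That list had a median of -0.83 (adjusted p = 6.55e-12, adjusted p = 0.181 with an estimated correlation). Of 23 genes of fatty acid and triglyceride synthesis 3 fell, 10 adjusted over the list alone: ATPCL (18940 ± 1934 to 8708 ± 654; log2 -1.12, SE 0.20, adjusted p = 0.00693), the acyltransferase mino (log2 -0.94, SE 0.15, adjusted p = 0.00322) and the acyl-CoA synthetase Acsl (log2 -0.82, adjusted p = 0.0104; not called under library totals). Its median was -0.43 and it kept its call with an estimated correlation (adjusted p = 1.84e-08, adjusted p = 0.0175 with an estimated correlation). ATPCL overlaps CG8320 and mino overlaps NSD, so their reads may include these genes. Acox57D-d fell by 1.42 on the log2 scale (adjusted p = 0.000739). The clotting factor gene fon fell by 0.68 (104000 ± 8700 to 65110 ± 5440, adjusted p = 0.00532), not under library totals, and Drat fell to 0.190 times (8454 ± 2456 to 1627 ± 627; log2 -2.40, SE 0.47, adjusted p = 0.0112).

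The remaining lists that passed between Toll10b+myrAkt and control lost their calls with an estimated correlation. Higher were antimicrobial peptides (1 of 13 rose, Dro, lost in 6 of 16 fits; median 1.51, or 0.49 without controls 1 and 2, where the list call was lost at 0.398; adjusted p = 9.27e-05, adjusted p = 0.473 with an estimated correlation), cell cycle and DNA replication (1 of 21, dpa, lost in 12 of 16 fits; 0.99, 0.0015, and 0.471) and hemocyte markers (1 of 11, NimC1, lost without control 4, 0.0541, or Toll10b+myrAkt 3, 0.0517; 0.93, 0.0412, and 0.647). The hemocyte list itself was lost without control 1 (0.0841), control 4 (0.205), Toll10b 2 (0.0528), myrAkt 3 (0.0518), Toll10b+myrAkt 3 (0.122) or Toll10b+myrAkt 4 (0.124). Lower were oxidative phosphorylation (1 of 70 fell, ND-13A, lost in 12 of 16 fits; median -0.47, adjusted p = 9.21e-18, adjusted p = 0.471 with an estimated correlation) and endoplasmic reticulum chaperones (1 of 27, Herp; -0.22, 5.97e-05, and 0.473). Also lower were heat shock proteins (1 of 17, Hsp70Bb; -0.69, 0.000426, and 0.473), lipolysis and beta-oxidation (1 of 13, Acox57D-d; -0.35, 0.00243, and 0.471) and insulin-like peptides and growth signals (0 of 19; -0.31, 0.00468, and 0.225). The same held for larval serum proteins (0 of 9; -0.31, 0.0193, and 0.358; lost without control 2, 0.0583, or Toll10b+myrAkt 1, 0.0686) and trehalose and glycogen (median -0.33 and mean 0.06, since tobi rose; 0.00947, and 0.471; lost without Toll10b+myrAkt 4, 0.0553). Cytosolic ribosomal proteins (median -0.11, adjusted p = 4.79e-06, adjusted p = 0.473 with an estimated correlation) and mitochondrial ribosomal proteins (-0.14, 0.00162, and 0.809; lost without control 1, 0.0916) were lower, but by library totals their medians were 0.05 and 0.02. The calls of Herp, ND-13A and dpa also ended under library totals. For heat shock proteins the mean log2 level was 9.83 and 10.34 in controls 1 and 2. It was 7.49 and 6.94 in controls 3 and 4, near the mean of 7.21 in Toll10b+myrAkt, so the lower level rests on controls 1 and 2.

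Over all genes 163 were higher and 207 lower, 54 of the 370 in a fixed list. Outside the immune lists, Tl and Akt, 136 of 350 lay on chromosome 2 and 155 on chromosome 3 (38.9% and 44.3%). Both chromosomes carried a transgene that differed here, so for the genes on them these shares do not decide about line background. Chromosome X, which carried no transgene that differed, held 50 of the 350. The higher genes numbered 85 without control 2, 88 without control 4, 91 without Toll10b+myrAkt 3 and 100 without Toll10b+myrAkt 4, and the lower genes 109 without control 4 and 135 without Toll10b+myrAkt 3. Library totals alone gave 282 higher and 96 lower with the median of all genes at 0.22, while TMM scaling gave 175 and 175 with it at 0.10. Without the libraries richest in salivary gland markers 70 and 125 passed, without those richest in gut markers 68 and 81.

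**Figure D4:**
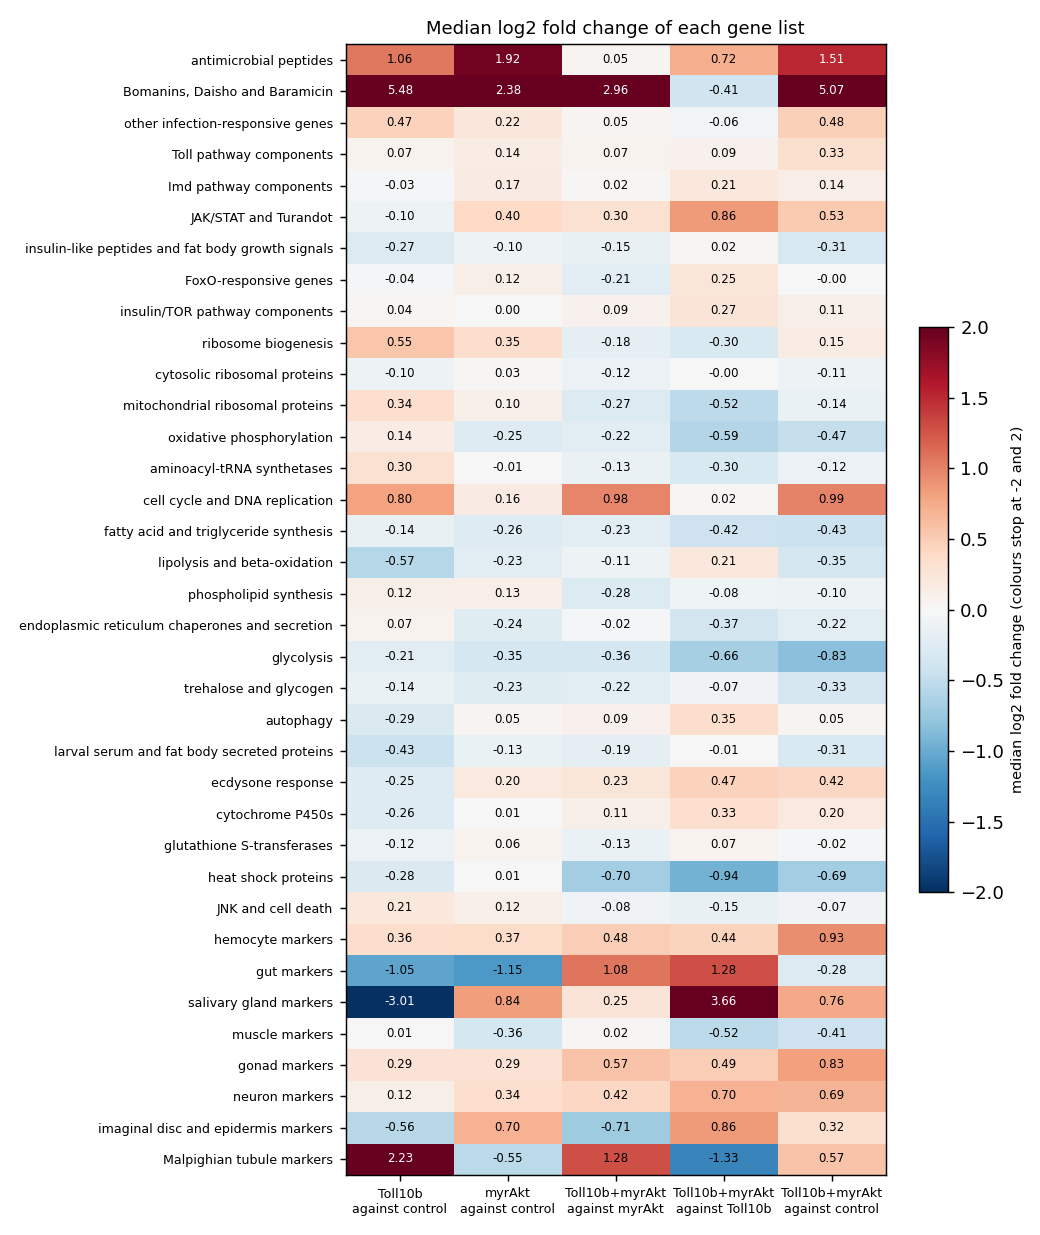
Median log2 fold change of each gene list in 5 comparisons, as numbers and colours, with colours ending at -2 and 2. The Bomanin list reached 5.48 for Toll10b against control and 5.07 for both transgenes against control, and glycolysis was -0.83 in the latter; by library totals the cytosolic ribosomal, fatty acid synthesis, glycolysis and trehalose medians for Toll10b against control were positive.

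The interaction asks whether the effect of Toll10b depended on myrAkt. No gene passed with limma (smallest adjusted p = 0.877; 465 genes at an unadjusted p under 0.05 where 559 would be expected by chance), and the count was also 0 with edgeR (358 unadjusted with TMM, 379 with RLE), DESeq2 (477), limma-voom (599) and the replicate block (871). BomS3 gave -2.78 (SE 1.01, adjusted p = 0.877). As sets, Bomanins, Daishos and Baramicins were negative in 15 of 17 members (median -2.89, or -1.65 without controls 1 and 2; 10 lower adjusted over the list alone, adjusted p = 1.06e-13, adjusted p = 0.219 with an estimated correlation), as were antimicrobial peptides (13 of 13, -1.09, 0.00481, and 0.665; lost without control 1, 0.089, control 2, 0.198, Toll10b 3, 0.0584, or Toll10b+myrAkt 1, 0.153; the median was 0.20 without controls 1 and 2). Also negative were mitochondrial ribosomal proteins (median -0.66, adjusted p = 2.9e-21, adjusted p = 0.512 with an estimated correlation), ribosome biogenesis (-0.76, 1.47e-05, and 0.664) and oxidative phosphorylation (-0.35, 2.31e-08, and 0.665). So were aminoacyl-tRNA synthetases (-0.39, 7.73e-05, and 0.664), other infection-responsive genes (-0.34, 0.0196, and 0.694; lost in 7 of 16 fits, and 0.09 without controls 1 and 2) and JNK and cell death (-0.51, 0.0177, and 0.635; lost without control 1, 0.0837, Toll10b 1, 0.0922, or Toll10b+myrAkt 4, 0.0598). Positive were lipolysis and beta-oxidation (median 0.35, adjusted p = 0.000129, adjusted p = 0.512 with an estimated correlation), autophagy (0.36, 0.000325, and 0.512), ecdysone response (0.41, 0.0093, and 0.219), cytochrome P450s (0.41, 0.00185, and 0.512) and gut markers (1.84, 0.0448, and 0.664; 0.453 without control 4). With an estimated correlation, the only list calls that held in the 6 comparisons were the Bomanin list for Toll10b and for both transgenes against control, and fatty acid synthesis for both transgenes against control.

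The differences with Toll10b and with myrAkt were each measured without and with the other transgene, in separate libraries. The same transgene chromosome differed each time, so line background would recur as well. Shared signs and calls therefore do not separate a transgene effect from line background. The Toll10b effects without and with myrAkt correlated across 11181 genes with a Pearson r of 0.391 and a Spearman rho of 0.189, which carry no p since genes are not independent replicates. All 101 genes called for Toll10b had the same sign with myrAkt and 96 had a smaller fold change, with a median ratio of 0.64; 11 higher and 7 lower genes were called both times, against 0.0726 and 0.0346 for unrelated lists. The myrAkt effects without and with Toll10b correlated at 0.379 and 0.291; all 41 called genes kept their sign, 28 were smaller, and 14 higher and 15 lower were called both times. Toll10b and myrAkt against the shared controls had 1 higher and 1 lower called gene in common, against 0.10 and 0.08 for unrelated lists, and across genes correlated at 0.348. Groups simulated without change, with the controls also drawn anew from the control means, gave a mean of 0.505. With the real controls split between both comparisons the mean was -0.03. The shared higher count was 0 without Toll10b 1 or 3, 2 without control 1, myrAkt 2 or Toll10b+myrAkt 4, and 3 without Toll10b 2, and the shared lower count was 2 without control 3 or Toll10b 4.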

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

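The test for a sample standing far from the other 3 of its group was set before the data were examined. It covered 131 groups of gene values for 52 named genes, 148 groups of list levels and 4 groups of depths. The named genes followed the rule fixed in advance, mostly through their calls in these data. The list levels included the Malpighian tubule markers, which were added after the data had been seen. Of these 283 groups 18 held such a sample, where chance gives about 1 in 20, or 14.2.

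Toll10b 2 had the lowest Tl of its group, 4225 against 12530 to 13530 in the other 3. The same library had the lowest mean log2 level of Toll pathway components (8.915 against 9.496 to 9.61), other infection-responsive genes (9.502 against 10.75 to 10.93), insulin-like peptides and fat body growth signals (6.637 against 6.794 to 6.826) and FoxO-responsive genes (8.802 against 9.228 to 9.294). Its Bomanin level was 7.69 against 8.85 to 9.74, which did not stand apart by that test. These lists share a sample and are not separate events; no biological explanation was tested.

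Toll10b+myrAkt 3 had the highest BomBc1 of its group (4952 against 1680 to 2191), the highest BomBc2 (3382 against 1136 to 1239) and the highest mean log2 level of cytochrome P450s (5.538 against 5.31 to 5.346). Toll10b+myrAkt 4 had the highest Sod3 (569.2 against 405.8 to 430) and the lowest Unc-115b (504.9 against 871.9 to 936.2). Toll10b+myrAkt 2 had the highest Drat (2565 against 1251 to 1356), and Toll10b+myrAkt 1 the lowest level of larval serum and fat body secreted proteins (17.7 against 18.14 to 18.22).

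Among controls, control 2 had the lowest kel (840.7 against 1631 to 1707), and control 1 had the only p24-2 reads (11 against 0) and the highest ribosome biogenesis level (7.36 against 5.971 to 6.126). Gut markers were highest in control 4 (5.832 against 1.58 to 1.782), and the sex-linked dosage list, which is Sxl alone, in control 3 (10.98 against 10.74 to 10.76). Muscle markers were highest in Toll10b 4 (7.961 against 5.901 to 6.13).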

How the results depend on the processing

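Chosen only after the results were seen were the fits with TMM scaling, edgeR with TMM, other-tissue marker levels as covariates, the libraries richest in salivary gland or gut markers left out, thinned reads, pairs of controls left out, and the block with only the compared groups; the other alternatives were planned. Of 184 gene results, 120 of them called, no called gene changed direction under any alternative. Calls lost and gained were 12 and 0 with edgeR RLE, 15 and 0 with edgeR TMM, 8 and 1 with TMM scaling, 30 and 0 with library totals, 0 and 5 with DESeq2, 5 and 4 with limma-voom, 9 and 0 without a filter, 0 and 3 with the 5 CPM filter (174 results, 116 called, had a value there), 7 and 0 with a pseudocount of 0.1, 44 and 0 with only the compared groups (181 results, all but the 3 of the interaction), 1 and 3 with the replicate block, 61 and 0 with marker covariates, 49 and 0 without salivary-rich libraries, 52 and 0 without gut-rich libraries and 14 and 0 with thinned reads. With a library left out 437 of 1920 called results were lost. The cause was not tested, except that leaving out samples or groups leaves fewer samples.

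DESeq2 gave more calls: 121 higher and 92 lower for Toll10b against control (main 58 and 43), 54 and 79 for myrAkt against control (20 and 21), 42 and 39 for Toll10b+myrAkt against myrAkt (14 and 9), 222 and 242 against Toll10b (61 and 45), and 371 and 409 against control (163 and 207). Limma-voom gave more lower genes, 84, 32, 27, 95 and 319 in that order. Library totals gave 20 lower genes for Toll10b, 3 for Toll10b+myrAkt against myrAkt, and 282 higher and 96 lower for Toll10b+myrAkt against control. The cause was not tested.

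Replicate numbers were not treated as pairs, since 16 of 24 same-number correlations were over 0.1 and not all (-0.29 to 0.50, median 0.18). Yet 11 of 16 samples correlated best with their own number, although most samples they were compared with had another number. All 4 pairs of Toll10b+myrAkt and myrAkt were over 0.1 (0.17 to 0.43). This hints, from the data and not the design, that numbers share some handling. The reported counts and p-values do not take such handling into account. As a block the replicate numbers gave 102 higher and 95 lower genes for Toll10b, 40 and 46 for myrAkt, 204 and 177 for Toll10b+myrAkt against Toll10b, and 320 and 346 against control, with 6 higher and 6 lower genes shared by Toll10b and myrAkt. For Toll10b+myrAkt against myrAkt the block gave 14 and 13, and 14 and 3 with only these groups in the fit. Of the latter 17 genes only 7 were among the 23 reported, and 4 of 9 named calls were lost: ATPCL (adjusted p = 0.072), Cyp6a23 (0.077), Cyp4ac1 (0.133) and Sod3 (0.147). The cause was not tested.

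With fewer samples, the compared groups alone gave 13 higher genes for myrAkt, 1 lower for Toll10b+myrAkt against myrAkt, 12 higher and 7 lower against Toll10b, and 91 and 120 against control. Without salivary-rich libraries there were 32 higher and 25 lower for Toll10b, 7 and 2 for Toll10b+myrAkt against myrAkt, and 70 and 125 against control. Without gut-rich libraries there were 17 lower against myrAkt, 14 higher and 12 lower against Toll10b, and 68 and 81 against control. Marker covariates gave 18 and 7 for Toll10b, 10 and 8 for myrAkt, 0 and 0 for Toll10b+myrAkt against myrAkt, 11 and 7 against Toll10b, and 132 lower against control; the cause was not tested. A minimum absolute log2 fold change of 1 left 19 lower genes for Toll10b, 12 for myrAkt, 29 for Toll10b+myrAkt against Toll10b and 89 against control, by construction. For Toll10b+myrAkt against myrAkt the 5 CPM filter gave 9 higher and 14 lower and the pseudocount of 0.1 gave 7 higher. That filter tests fewer genes and moved the correlations of the Toll10b and myrAkt effects to 0.597 and 0.559 and the shared higher genes to 2.

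Tl in Toll10b lost its call at a log2 fold change of 2.03 with only the compared groups, 1.90 with marker covariates and 1.94 without salivary-rich libraries. With an estimated correlation 1, 0, 0, 0, 2 and 0 lists were called in the 6 comparisons, and with fry 3, 0, 2, 7, 7 and 0 (main 17, 8, 9, 13, 15 and 13). Directions reversed for cytosolic ribosomal proteins under library totals (adjusted p = 0.0539 for Toll10b against control, 0.958 for Toll10b+myrAkt against control) and, with marker covariates, for Malpighian tubule markers in Toll10b (0.534) and antimicrobial peptides in Toll10b+myrAkt against myrAkt (0.0229). Without controls 1 and 2 they reversed for antimicrobial peptides (0.127 in Toll10b, 0.281 in the interaction) and other infection-responsive genes (0.431 and 0.547). The Bomanin list kept its direction and, at the preset correlation, its calls against control and in the interaction with any pair of controls left out. With an estimated correlation and all controls, its calls in myrAkt against control (0.343) and in the interaction (0.219) were lost. Lists without a call that changed sign are not counted here. The cause was not tested.

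With each library left out in turn, counts of higher and lower genes ran from 29 to 84 and 22 to 46 for Toll10b, 13 to 24 and 15 to 28 for myrAkt, 7 to 20 and 0 to 22 for Toll10b+myrAkt against myrAkt, 11 to 85 and 9 to 63 against Toll10b, and 85 to 194 and 109 to 214 against control. The interaction stayed at 0 with limma. Tl ran from 1.84 to 2.43, Ilp6 from -1.09 to -0.72 and Akt from 3.24 to 3.43. Lists called ran from 13 to 19, 7 to 10, 9 to 15, 12 to 17, 13 to 18 and 10 to 15, and 85 of 1200 list calls were lost. The correlations ran from 0.291 to 0.478 and 0.281 to 0.407, and the shared genes from 0 to 3 and 1 to 2. Thinned to 10.3 M reads, Toll10b+myrAkt against control called 345 genes in place of 370.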

Other observations

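Chosen only after the results were seen were the tests of all Bomanin list members, of the Bomanin level with myrAkt alone, of pairs of controls and of the chromosomes, and the fits with thinned reads and with marker levels; the others were written down beforehand.

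The Bomanin, Daisho and Baramicin genes had a smaller estimated rise with Toll10b when myrAkt was present (median log2 2.96 against 5.48, interaction -2.89, negative in 15 of 17), but no gene passed (smallest adjusted p = 0.877) and the list lost its interaction call with an estimated correlation (0.219). Selection of members by their change is argued against only because this list was fixed beforehand and all measured members counted. The 88.2% that were negative are the same 15 of 17 and no separate test. For the 96 of 101 called genes with a smaller fold change, selection cannot be told apart. Of the 23 genes called in Toll10b+myrAkt against myrAkt, 30.4% were smaller in Toll10b against control, which fell between the bounds set beforehand. Low immune expression in the controls cannot be told apart: controls 1 and 2 were both low (mean log2 level 2.61 and 2.70, against 4.62 and 4.47), so the -2.35 or lower with any single control left out decides nothing, and without both the median interaction was -1.65, still negative in 15 of 17. A raised starting level with myrAkt alone cannot be told apart from this either: its median of 2.38 was 5.88 times the size of the -0.40 in Toll10b+myrAkt against Toll10b, but 2.45 to 8.21 times with pairs of controls left out, and Akt activity, untested here, stays open too.

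Called genes lay on the chromosome of the transgene that differed. Line background on chromosome 3, which a parent with UAS-myrAkt may carry in place of that of the parent with UAS-GFP, had the excess it needs (35 of 40 genes, Fisher's exact p = 5.56e-09), and so did chromosome 2 for Toll10b (57 of 86, p = 2.72e-07). Direct targets of Akt or Toll would have no evident reason to share the transgene's chromosome, but this biological alternative was not tested. Immune genes were left out of these counts, and BomBc1 and Dso1 themselves lie on chromosome 2R, so the chromosome test does not separate their response from line background. Single genes such as tobi, p24-2, Unc-115b and cpx therefore stay open between both readings. So do the genes called for Toll10b on chromosome 2, such as Cyp12d1-p, Cyp6a23 and Cyp6a2.

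More genes were called between Toll10b+myrAkt and control (370) than for Toll10b (101) or myrAkt (41). Deeper libraries are argued against: with all libraries thinned to 10.3 M reads the counts were 345, 88 and 36, the first being 3.92 times the second. Other-tissue RNA as the whole cause is argued against by a median ratio of fold changes of 1.02 with marker levels in the fit, where 271 genes were called. The sum of the separate effects came to 0.7997 of the joint effect (0.742 to 0.933 over 6 splits of the controls). The mean fell just under the lower bound set beforehand for this cause, and all splits lay above the bound set against it, so it cannot be told apart. Genes were ranked with the same Toll10b+myrAkt libraries that gave the joint effect, which can enlarge that effect and lower the ratio. The genes of this comparison showed little excess on either transgene chromosome. The shares were 38.9% on chromosome 2 and 44.3% on chromosome 3, against 38.5% and 42.8% of tested genes. Both chromosomes carried a transgene that differed here, so an excess from line background could be split between them. For the genes on chromosomes 2 and 3 these shares do not decide about it. Chromosome X, which carried no transgene that differed, held 50 of the 350 genes. Background that changes only genes on chromosomes 2 and 3 would not reach these 50. Called here too were 42 of 58 higher and 33 of 43 lower genes of Toll10b. For myrAkt they were 20 of 20 and 19 of 21.

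Of the 35 splits of the same 8 samples, the real labels gave the most calls in each pairwise comparison, the smallest share this test can give. Chance is argued against at that level for Toll10b (101 genes, highest other split 3), myrAkt (41, 1), Toll10b+myrAkt against Toll10b (106, 1) and against control (370, 11), each in 1 of 35. It is not excluded, since that share is not adjusted over the comparisons. The test also treats the samples as exchangeable, while 11 of 16 correlated best with a sample of their own number. For Toll10b+myrAkt against myrAkt the real 23 was also reached in 1 of 35, but another split, replicates 1 and 3 of both groups against 2 and 4, gave 18, so the margin is small and the count is left open; of the 8 splits that part all same-numbered samples the highest other gave 0. For the interaction the real count was 0, so all 100 of 100 drawn regroupings of the 16 samples gave as many by construction, and nothing about chance follows. The highest gave 432. Regrouping all samples can mix the differences between the real groups into the contrast, but whether this gave that count was not tested.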
